A study of Homo sapiens with 12 samples.

How the data were processed

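Vesicles came from human left ventricle, their RNA was extracted with the miRNeasy Mini Kit, and libraries were made with the QIAseq miRNA Library Kit, per the labels' protocols. This kit tags each molecule before amplification, so that the counts are of molecules and not of PCR copies. The 12 libraries fall into 6 failing (non-ischemic heart failure) and 6 non-failing samples, and the group and number of each library were taken from its title. The labels speak of patients but do not say that each sample came from a different one, so p-values measure the spread between these samples.

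The authors deposited 1 table with UMI counts per mature miRNA. Per the file headers, reads were trimmed in 2 rounds, counted as UMI reads, grouped on the mature miRNA and annotated. The build is hg38 per the labels, and the aligner, the miRNA database release and the program are not given in the sources used here. A second set of columns headed CPM holds a deposited signal, each count divided by a library size that includes a composition factor. That factor equals the TMM factor over all rows. The same table holds the authors' own comparison: a deposited log2 fold change, a signed fold change as a score, p-values and FDR-adjusted p-values. The tool behind it is not given in the sources used here. RPKM and TPM columns of the same libraries were not used here. The counts were used as deposited.

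Total UMI counts ranged from 6066 to 77364 per library. A count of 0 allows a share of up to 3 counts of the total, which is 0.0495% in the smallest and 0.00388% in the largest library. Shares of single libraries carry 95% Wilson intervals, which cover counting error only. The most alike pair of libraries within a group, non-failing 1 and 4, differed by a chi-square of 6.39 per degree of freedom, beyond counting error.

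Counts were tested in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 104 miRNAs, and the rows left out held 2.57% ± 0.545 of counts in failing and 3.83% ± 1.37 in non-failing libraries. Libraries were scaled by TMM, and a quasi-likelihood model with group as its only term was fitted to all 12 libraries. Tests were two-sided with Benjamini-Hochberg adjustment. Log2 fold changes are failing over non-failing, and their standard errors are the absolute log2 fold change divided by the square root of the F statistic. The CPM values given are TMM-scaled. The biological coefficient of variation was 0.749.

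Before the data were examined, 21 miRNA lists were fixed from general knowledge of tissue distribution, families and clusters. They were muscle-enriched, fibroblast and fibrosis-associated, miR-29, endothelial, smooth muscle and pericyte, erythroid, leukocyte and platelet, let-7, miR-30, miR-17~92, miR-15/16, miR-23/24/27, miR-99/100 and miR-125, miR-181, miR-34 with miR-449, miR-212 and miR-132 with miR-210, 14q32, epithelial, liver, neural and heart failure miRNAs. A miRNA can be in more than 1 list. The 13 lists with at least 3 tested members entered camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. The share of counts of each of the 21 lists and 7 library measures were compared by an exact permutation test of the difference of group means over all assignments of the libraries, two-sided.

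The miRNAs named were chosen by a rule fixed beforehand. It took up to 10 per direction with the largest change past an adjusted p of 0.05, or, where fewer than 10 passed, the 10 with the smallest p, then the 2 members with the smallest p of every list with at least 3 tested members, and the 10 with the highest mean CPM. Other miRNAs are named where they belong to a small count or a list described, and were chosen after their values were seen.

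Precursor positions, host genes and GC content were taken from GENCODE release 29 (GRCh38) by the precursor names of each mature miRNA, with Python 3.11.15. A GC value was found for 102 of the 104 tested miRNAs. miR-10400-5p has none, and its position is not reported here.

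The code was tested on simulated counts for the 687 miRNAs of this comparison, with the mean shares, library sizes and dispersions of these libraries and 200 changed miRNAs per run in 20 runs. Of the tested changed miRNAs it recovered 19.0% at 2-fold, 69.7% at 4-fold and 92.0% at 8-fold, and it called 0.769% of the unchanged. With no change, 4.86% of unadjusted p-values lay under 0.05 and a list passed in 0 of 20 runs. Each miRNA was drawn independently, whereas the members of the fibroblast list had an estimated correlation of 0.356. The 0 of 20 thus says nothing on list calls among correlated members. Each simulated miRNA also had 1 dispersion for both groups. In the libraries some miRNAs spread more among non-failing samples, such as miR-3960 (57184 ± 91245 CPM, against 1725 ± 854 in failing). The recovered and called percentages may not hold for such miRNAs.

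The alternatives were RLE, upper-quartile and library-total scaling, no count filter, a mean CPM of at least 10, DESeq2 1.42.0, limma-voom with and without quality weights, robust estimation, the replicate number as a block, each library left out in turn, an adjusted p of 0.10 and a minimum change of 2-fold. Alternatives added after seeing the data left out non-failing libraries 2 and 6, libraries 2, 5 and 6, or the GC-rich rows with miR-10400-5p, miR-10396b-5p, miR-10396b-3p and miR-12136, or thinned every library to 6066 counts in 20 draws. The group of miRNAs with a precursor GC of at least 70% was also formed then. Shares among counts outside GC-rich precursors also left out miR-10400-5p, miR-10396b-5p, miR-10396b-3p and miR-12136, for which no GC value was found.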

Results

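The miRNA cargo of matrix-bound extracellular vesicles was measured in 6 failing and 6 non-failing samples of human left ventricle. Matrix-bound vesicles are membrane-enclosed particles embedded in the extracellular matrix of a tissue, in contrast to vesicles free in body fluids. The failing samples came from non-ischemic heart failure, a loss of pump function without coronary artery disease as its origin. Molecules were counted with unique molecular identifiers (UMIs), random tags that let PCR copies of 1 molecule be counted once. Of 2632 mature miRNAs listed, 687 had at least 1 count in the 12 libraries. Total UMI counts were 77364, 43099, 32353, 27472, 53982 and 26349 in failing libraries 1 to 6, and 14153, 22062, 11959, 12986, 34995 and 6066 in non-failing libraries 1 to 6. The failing libraries were thus 2.55-fold deeper on average (exact permutation test of the means, two-sided, p = 0.0108, adjusted over 7 library measures p = 0.0379). More miRNAs were detected in failing libraries, 349 ± 28.7 against 257 ± 49.1 (SD, n = 6 per group, exact permutation p = 0.00433, adjusted p = 0.0303). At an equal depth of 6066 counts the numbers were 193 ± 13.6 and 191 ± 20.3 (exact permutation p = 0.816). The 10 most abundant miRNAs of each library held 62.2% ± 6.38 of the counts in failing and 64.9% ± 8.10 in non-failing libraries, a difference within the spread between libraries (exact permutation p = 0.543).

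The most abundant miRNAs by mean CPM over all libraries were let-7b-5p, miR-4516, miR-199a-3p, let-7a-5p, miR-378a-3p, miR-143-3p, miR-4488, miR-125b-5p, let-7i-5p and let-7f-5p. For miR-4516, miR-378a-3p and miR-4488 the rank came from non-failing libraries. Their means were 18433, 4063 and 6107 CPM in failing and 137554, 103583 and 96804 in non-failing libraries. let-7b-5p, a member of the let-7 family of growth-restraining miRNAs, stood at 87699 ± 27096 CPM (counts scaled to library size, SD, n = 6) in failing and 132131 ± 151848 in non-failing libraries. let-7b-5p reached 440227 CPM in non-failing library 5 and 49765 to 96364 in the other non-failing libraries. Without library 5 its log2 fold change was 0.37 in place of -0.59. Its precursor MIRLET7B lies in an exon of MIRLET7BHG at chromosome 22, 46113686 to 46113768 (GRCh38). miR-199a-3p, whose mature sequence is shared with miR-199b-3p so that the copies cannot be told apart, stood at 89778 ± 14885 CPM in failing and 57355 ± 24565 in non-failing libraries. miR-143-3p, a miRNA of smooth muscle cells encoded in an exon of CARMN on chromosome 5, differed little, with 56160.4 ± 10056 CPM against 47415 ± 12873. let-7a-5p, let-7f-5p and miR-125b-5p had log2 fold changes of 0.29, 0.11 and 0.41, with standard errors of 0.40, 0.33 and 0.46. For let-7b-5p, miR-199a-3p, miR-143-3p, let-7a-5p, let-7f-5p and miR-125b-5p, no difference exceeded the spread between libraries in edgeR's quasi-likelihood test (adjusted p from 0.388 to 0.811).

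**Figure D1:**
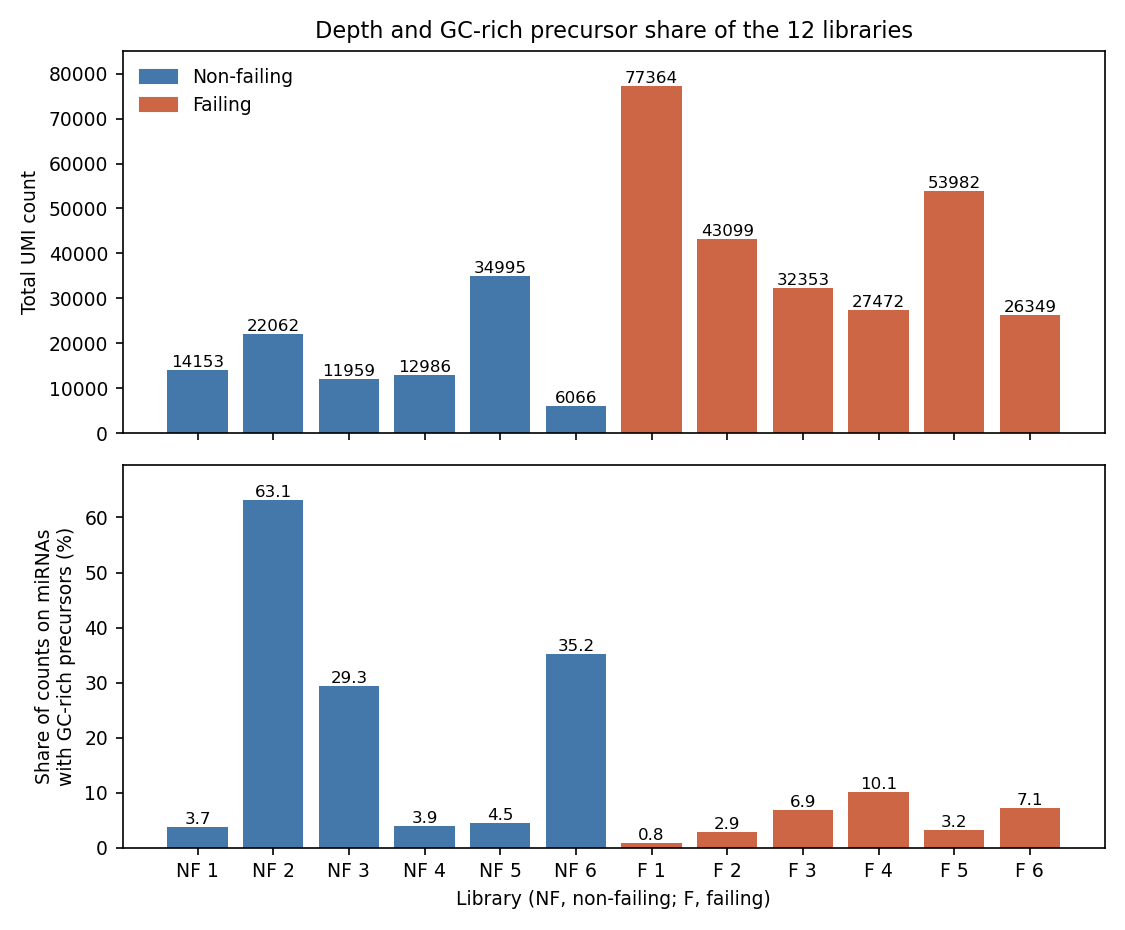
Total UMI count (upper panel) and share of counts in percent on miRNAs whose precursor has at least 70% GC (lower panel), 1 bar per library, for the 6 non-failing (NF) and 6 failing (F) libraries. Non-failing libraries 2, 3 and 6 had GC-rich shares of 63.1%, 29.3% and 35.2%, and the failing libraries lay between 0.792% and 10.1%.

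The central comparison asked whether the vesicle cargo of failing hearts differs from that of non-failing hearts. miR-23a-3p, which is processed from 1 transcript with miR-27a and a copy of miR-24, was 1.98-fold higher in failing libraries, at 8554 ± 1208 CPM against 4318 ± 762 (SD, n = 6 per group). Every failing library exceeded every non-failing library for this miRNA. miR-195-5p of the miR-15/16 family was 2.09-fold higher, miR-199b-5p 1.82-fold higher and miR-152-3p 1.73-fold higher, each above the non-failing median in 6 of 6 failing libraries. Lower levels were measured for miR-223-3p, a miRNA of neutrophils, monocytes and platelets (429 ± 123 against 2552 ± 2941 CPM), and for miR-486-5p, a miRNA abundant in red blood cells (1169 ± 403 against 5302 ± 5306 CPM). Mean levels were also far lower for miR-10400-5p, miR-4492, miR-3960, miR-4488 and miR-4508, the last 4 of which come from GC-rich precursors, and for the muscle-enriched miR-378a-3p. These means leaned on a few non-failing libraries. Without libraries 2 and 6, left out after seeing the data, the log2 fold change of miR-10400-5p was -0.95 in place of -6.26. For miR-378a-3p it was -1.89 without library 5 in place of -4.67. There, 3 of 6 failing libraries lay above the non-failing median with all libraries, against 0 of 6 for each of the others.

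None of these differences passed an adjusted p of 0.05: edgeR's quasi-likelihood test called 0 of the 104 miRNAs with enough counts, whereas 28 had an unadjusted p under 0.05, 7 higher and 21 lower in failing. DESeq2 gave no adjusted p for 6 of the 104. It called 23 of the same miRNAs (6 higher and 17 lower), and limma-voom called 1, miR-23a-3p. The smallest adjusted p was 0.0583, shared by 6 miRNAs, and 23 miRNAs had an adjusted p under 0.10, 5 higher and 18 lower. The median 95% interval reached 1.02 on the log2 scale to either side, a 2.03-fold change. The groups did not overlap for 2 miRNAs, miR-23a-3p and miR-199b-5p, where chance gives a share of 0.00216 per miRNA.

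Of the 10 miRNAs with the smallest p, none of which passed in edgeR's quasi-likelihood test, 5 were these. miR-23a-3p (precursor MIR23A, chromosome 19, 13836587 to 13836659, in an exon of AC020916.1) had a log2 fold change of 0.99 with a standard error (SE) of 0.23 and an adjusted p of 0.0583. miR-223-3p (MIR223, chromosome X, 66018870 to 66018979) had a log2 fold change of -2.58 (SE 0.71, adjusted p = 0.0583; -1.75 without non-failing library 4) and counts of 3 to 130 per library in non-failing and 8 to 34 in failing libraries. miR-486-5p, from the overlapping precursors MIR486-1 and MIR486-2 in an intron of ANK1 at chromosome 8, 41660441 to 41660508, had a log2 fold change of -2.19 (SE 0.65, adjusted p = 0.0620). miR-152-3p, from an intron of COPZ2 at chromosome 17, 48037161 to 48037247, had a log2 fold change of 0.79 (SE 0.24, adjusted p = 0.0620). miR-671-5p, from an exon of CHPF2 at chromosome 7, 151238421 to 151238538, had a log2 fold change of -3.45 (SE 1.01, adjusted p = 0.0620). Without non-failing library 5, where it reached 16525 CPM, the value for miR-671-5p was -2.03.

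The other 5 of the 10 were high in a few non-failing libraries. miR-3960, from an exon of CDK9 at chromosome 9, 127785833 to 127785923, had a log2 fold change of -5.05 (SE 1.33), and its precursor has 87.9% GC. miR-4492 (chromosome 11, 118910708 to 118910787, opposite an exon of BCL9L) stood at -5.77 (SE 1.59), miR-10400-5p at -6.26 (SE 1.74), miR-4508 (chromosome 15, 23562062 to 23562131, outside annotated genes) at -3.94 (SE 1.10) and miR-4488 (chromosome 11, 61508596 to 61508657, also outside annotated genes) at -3.99 (SE 1.23). Adjusted p-values were 0.0583 for the first 4 and 0.0703 for miR-4488. miR-3960 took 9.78% of the counts of non-failing library 2 (95% Wilson interval 9.39 to 10.2) and 7.11% of library 6 (6.49 to 7.78), but 0.198% of library 1 (0.137 to 0.286). Without non-failing libraries 2 and 6, a fit added after seeing the data, the log2 fold changes of miR-3960, miR-4492, miR-10400-5p, miR-4508 and miR-4488 were -1.32, -1.67, -0.95, -1.24 and -1.98. In that fit 2 miRNAs passed, miR-23a-3p and miR-432-5p of the 14q32 cluster, both higher in failing.

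**Figure D2:**
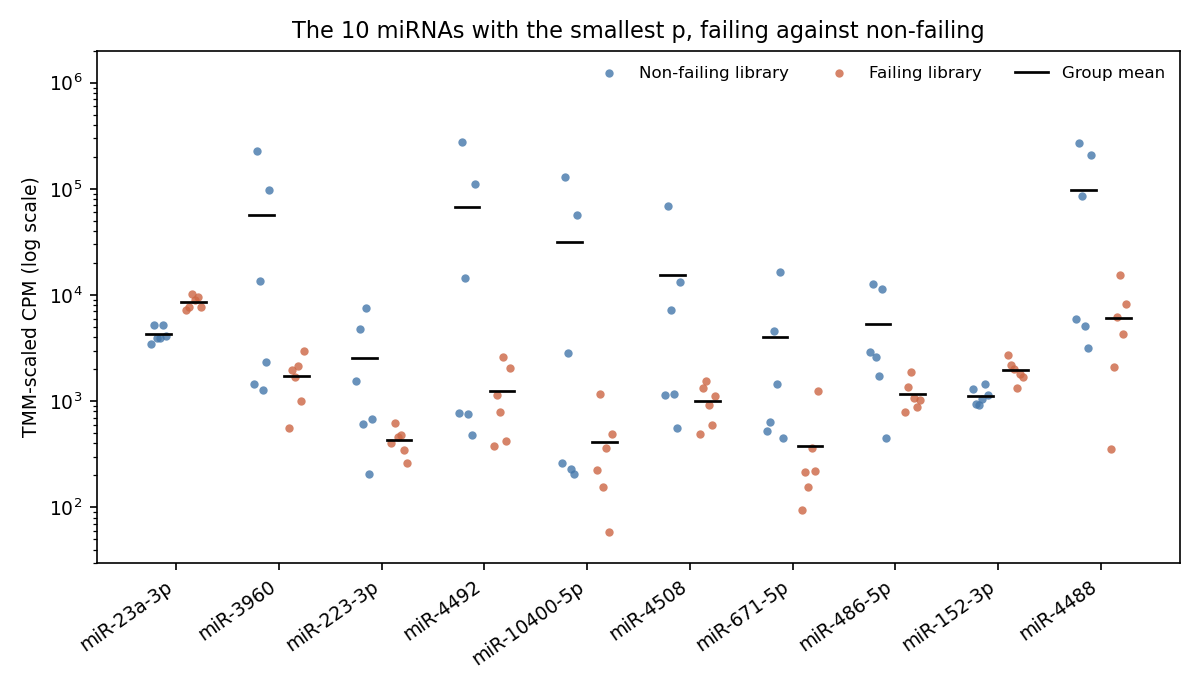
TMM-scaled CPM on a log axis for the 10 miRNAs with the smallest p, with 1 point per library (6 non-failing, 6 failing) and a line at each group's arithmetic mean. miR-23a-3p separated the groups, while for miR-3960, miR-4492 and miR-10400-5p the non-failing mean rested on libraries 2 and 6.

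Fibroblast and fibrosis-associated miRNAs formed the only list that passed limma's camera test with a preset correlation (adjusted p = 0.00691), and adjusted p = 0.538 with an estimated correlation, so that the call was lost there. Of 7 tested members 6 were higher in failing, with miR-10b-5p at a log2 fold change of 1.31 (SE 0.52), miR-199b-5p at 0.87 (SE 0.29), miR-152-3p at 0.79 (SE 0.24) and miR-199a-3p at 0.65 (SE 0.41). miR-21-5p, the best known fibroblast miRNA of the failing heart, went the other way at -0.44 (SE 0.60), and 6 of 7 members were also above the median of all tested miRNAs under each of 4 scalings. In edgeR's quasi-likelihood test 0 members passed over all miRNAs and 3 had an unadjusted p under 0.05, DESeq2 called 3 (miR-199b-5p, miR-152-3p and miR-10b-5p), and 2 passed when adjusted over the list alone, miR-152-3p (adjusted p = 0.0376) and miR-199b-5p (0.0387). The list's share of counts was 13.4% ± 2.58 in failing and 6.92% ± 4.61 in non-failing libraries (exact permutation p = 0.0216, adjusted p = 0.0758). The camera call was also lost with scaling by library totals (adjusted p = 0.0801) and without non-failing library 5 (adjusted p = 0.111, and from 0.00519 to 0.0278 without any other single library), and 6 of 100 splits of the libraries gave a camera p as small.

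The miR-23/24/27 clusters took a larger part of the cargo in failing hearts. Their share was 2.93% ± 0.339 of counts in failing and 1.38% ± 0.540 in non-failing libraries (exact permutation p = 0.00216, the smallest possible with 6 libraries per group, adjusted p = 0.0455), and it was the only one of 21 list shares to pass. All 5 tested members lay above the median of all tested miRNAs under each scaling. miR-27b-3p, from an intron of C9orf3 at chromosome 9, 95085445 to 95085541, stood at 7425 ± 823 against 5641 ± 1821 CPM, a log2 fold change of 0.40 (SE 0.27). miR-24-3p, miR-27a-3p and miR-23b-3p had log2 fold changes of 0.21, 0.18 and -0.14. By camera the list did not pass (adjusted p = 0.229), and 1 member, miR-23a-3p, passed when adjusted over the list alone (adjusted p = 0.00514).

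Muscle-enriched miRNAs did not move together. miR-378a-3p, encoded in an intron of PPARGC1B at chromosome 5, 149732825 to 149732890, stood at 4063 ± 2439 CPM in failing and 103583 ± 217545 in non-failing libraries (log2 fold change -4.67, SE 1.57, adjusted p = 0.0821). miR-133a-3p, from MIR133A1 on chromosome 18 and MIR133A2 on chromosome 20, stood at 3939 ± 2013 against 31685 ± 62077 CPM (log2 fold change -3.01, SE 1.09, adjusted p = 0.0949). Non-failing library 5 held most of both, and without it the log2 fold changes were -1.89 and -0.68. Of the others, non-failing library 3 had 68806 CPM of miR-378a-3p, and libraries 1, 2, 4 and 6 had 452 to 3935. miR-1-3p, miR-499a-5p and miR-208b-3p, which are expressed by heart muscle cells, had log2 fold changes of -0.17, -0.11 and 0.42. The list took 5.09% ± 1.38 of counts in failing libraries and from 0.993% to 30.1% in non-failing libraries (exact permutation p = 0.331), camera gave an adjusted p of 0.785, and 2 of 5 members passed when adjusted over the list alone.

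miRNAs of blood cells went both ways. Of 6 tested leukocyte and platelet miRNAs 5 were lower under the TMM scaling and 3 under scaling by library totals, led by miR-223-3p and by miR-142-3p, a miRNA of all blood lineages (511 ± 230 against 1674 ± 1954 CPM, log2 fold change -1.75, SE 0.66, adjusted p = 0.0949). Without non-failing library 4 the log2 fold changes of miR-223-3p and miR-142-3p were -1.75 and -0.82. miR-342-3p was higher, with a log2 fold change of 1.04 (adjusted p = 0.0949). In edgeR's quasi-likelihood test these 3 had an unadjusted p under 0.05 and passed when adjusted over the list alone, and 0 passed over all miRNAs, where DESeq2 called miR-223-3p (adjusted p = 0.00163) and miR-142-3p (0.0303). For the list camera gave an adjusted p of 0.497. The list's share was 0.851% ± 0.265 in failing and 0.987% (0.177% to 3.18%) in non-failing libraries (exact permutation p = 0.937). Among erythroid miRNAs only miR-486-5p had enough counts for the test, so adjusting over the list alone left its unadjusted p of 0.00509 in edgeR's quasi-likelihood test unchanged. Over all miRNAs its adjusted p was 0.0620 in that test, and DESeq2 called it (adjusted p = 0.00284). Erythroid miRNAs took 0.180% ± 0.0711 of counts in failing and 0.396% ± 0.226 in non-failing libraries (exact permutation p = 0.0541, adjusted p = 0.123).

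Of vessel-associated miRNAs, DESeq2 called miR-126-5p (adjusted p = 0.0226), and edgeR's quasi-likelihood test called 0 and gave 1 an unadjusted p under 0.05. The 3 tested endothelial miRNAs were lower under each scaling, with miR-126-5p, from an intron of EGFL7 at chromosome 9, 136670602 to 136670686, at a log2 fold change of -1.20 (SE 0.44, adjusted p = 0.0949). miR-221-3p stood at -1.12 (SE 0.58). Non-failing library 5 again held the highest levels, and without it the values were -0.54 and 0.0253. The endothelial share was 3.86% ± 1.13 against 4.12% ± 2.06 (exact permutation p = 0.794), with a camera adjusted p of 0.229 and 0 members past when adjusted over the list alone. Smooth muscle and pericyte miRNAs took 7.11% ± 1.20 of counts in failing and 4.11% ± 1.65 in non-failing libraries (exact permutation p = 0.00649, adjusted p = 0.0606). Their 2 tested members went apart, with miR-145-5p at a log2 fold change of -1.29 (SE 0.62) and miR-143-3p at 0.24 (SE 0.28).

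Among miRNA families, 5 of 8 let-7 members were lower under TMM and 0 of 8 under scaling by library totals, with let-7i-5p at a log2 fold change of -0.60 (SE 0.36) and let-7b-5p at -0.59 (SE 0.56), the latter at 0.37 without non-failing library 5. The let-7 share was 30.6% ± 6.28 in failing and 22.2% ± 7.97 in non-failing libraries (exact permutation p = 0.0758), a difference of 8.42 points that was 1.94 among counts outside GC-rich precursors (exact permutation p = 0.626). In the miR-15/16 family, miR-195-5p (chromosome 17, 7017615 to 7017701, in an exon of MIR497HG) had a log2 fold change of 1.06 (SE 0.35, adjusted p = 0.0821) and passed when adjusted over the list alone (0.0301), whereas miR-16-5p stood at -0.55 (SE 0.48), and at 0.0316 without non-failing library 2. The family's share was 2.96% ± 0.441 in failing and from 0.303% to 4.03% in non-failing libraries (exact permutation p = 0.491). All 5 tested members of the miR-99/100 and miR-125 families lay above the median of all tested miRNAs, led by miR-100-5p from an intron of MIR100HG on chromosome 11 (3669 ± 1457 against 1281 ± 1000 CPM, log2 fold change 1.48, SE 0.64, adjusted p = 0.145) and miR-99a-5p (0.58, SE 0.38). Their share was 9.03% ± 4.08 against 4.92% ± 2.53 (exact permutation p = 0.0563). In the miR-17~92 clusters, miR-93-5p from an intron of MCM7 was lower (log2 fold change -0.91, SE 0.32, adjusted p = 0.0857, adjusted over the list alone 0.0377), and miR-92a-3p stood at -0.68 (SE 0.58), and at 0.0384 without non-failing library 2. In the miR-30 family, miR-30e-5p and miR-30c-5p, both with copies in introns of NFYC on chromosome 1, had log2 fold changes of -0.59 (SE 0.28) and -0.76 (SE 0.38). Of the miRNAs named in this paragraph, DESeq2 called miR-100-5p (adjusted p = 0.0447), miR-195-5p (0.0196) and miR-93-5p (0.0258). With no count filter edgeR called miR-100-5p (adjusted p = 0.0289).

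The antifibrotic miR-29 family gave no call, with miR-29a-3p at a log2 fold change of 0.33 (SE 0.41) and miR-29b-3p at -0.19 (SE 0.35). Of the imprinted 14q32 cluster, miR-381-3p and miR-379-5p had log2 fold changes of 0.81 (SE 0.52) and 0.60 (SE 0.44). The cluster's share was 0.818% ± 0.241 in failing and 0.462% ± 0.122 in non-failing libraries (exact permutation p = 0.00866, adjusted p = 0.0606). This difference of 0.356 points was 0.185 among counts outside GC-rich precursors (exact permutation p = 0.240). Among 16 tested miRNAs reported in heart failure plasma or tissue 8 were higher and 8 lower under TMM, and 12 higher under scaling by library totals. Their median log2 fold change was 0.08 and their mean -0.27, so that the summaries differ in sign. miR-423-5p, a proposed circulating marker of heart failure, stood at -1.87 (SE 0.77, adjusted p = 0.127) with all libraries and at -0.37 without non-failing library 5. Camera adjusted p-values were 0.908 for let-7, 0.748 for the miR-29 and miR-30 families, 0.585 for the miR-17~92 clusters, 0.229 for the miR-15/16 family and for the miR-99/100 and miR-125 families, 0.350 for 14q32 and 0.497 for the heart failure list.

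Shares of the smaller lists were low. The miR-181 family and the miR-34 family with miR-449 took 0.168% and 0.165% of counts in failing and 0.0775% and 0.0750% in non-failing libraries (exact permutation p = 0.0152 and 0.0195, adjusted p = 0.0758 for both). Shares in failing and non-failing libraries were 1.34% and 0.842% for the miR-29 family, 2.58% and 1.68% for the miR-30 family, 0.675% and 0.655% for the miR-17~92 clusters, and 17.4% and 10.7% for the heart failure list (adjusted p from 0.0779 to 0.937). Epithelial, liver-enriched and neural miRNAs, which mark other tissues, took 0.0197%, 0.0285% and 0.126% in failing and 0.0447%, 0.0239% and 0.119% in non-failing libraries. miR-212, miR-132 and miR-210 together took 0.0173% and 0.0186%, from 50 and 26 counts per group. With no count filter edgeR called miR-210-3p lower in failing (adjusted p = 0.0414).

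List shares depended on the GC-rich miRNAs. These took 63.1%, 29.3% and 35.2% of counts in non-failing libraries 2, 3 and 6. In non-failing libraries 1, 4 and 5 they took 3.73% to 4.50%, within the failing range of 0.792% to 10.1%. A measure added after seeing the data took counts outside GC-rich precursors and without miR-10400-5p, miR-10396b-5p, miR-10396b-3p and miR-12136. Among these counts the miR-23/24/27 share differed by 1.27 points (failing minus non-failing, exact permutation p = 0.00216, adjusted p = 0.0455). Differences were smaller there for the fibroblast list (4.35 points, exact permutation p = 0.0779, against 6.50), the heart failure list (3.77 against 6.73), the miR-30 family (0.482 against 0.898) and 14q32 (0.185 against 0.356). They were larger in size for endothelial (-1.25 against -0.259, exact permutation p = 0.102), erythroid (-0.494 against -0.216, exact permutation p = 0.0303), leukocyte and platelet (-0.431 against -0.136) and epithelial miRNAs (-0.0613 against -0.0251). The direction turned for the miR-15/16 family (-1.04 against 0.460) and the miR-17~92 clusters (-0.385 against 0.0195). It also turned for neural (-0.0365 against 0.00720) and liver-enriched miRNAs (-0.0206 against 0.00462). List members with GC-rich precursors were themselves left out there, among them miR-92b and miR-210-3p of the heart failure list. For the list of miR-212, miR-132 and miR-210 only miR-132 kept counts, so its 0.00778 cannot be set against -0.00133 for the whole list.

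**Figure D3:**
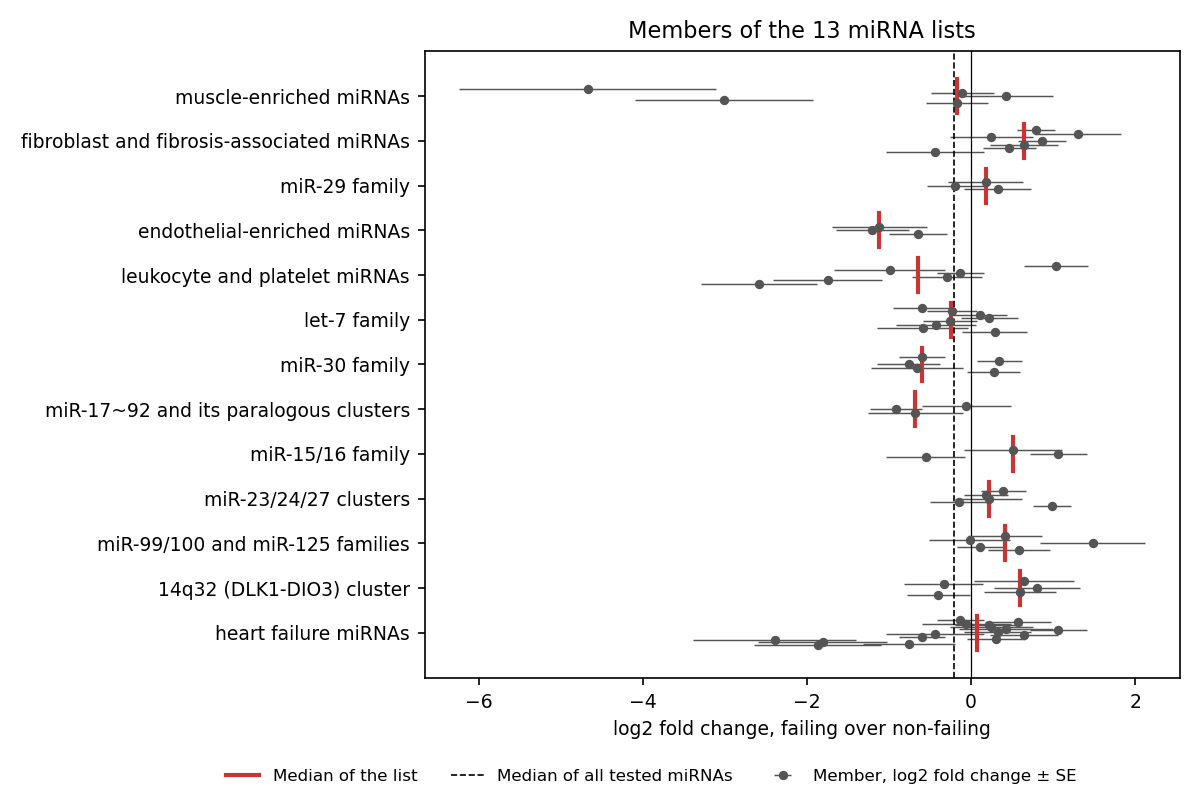
log2 fold change (failing over non-failing) with its standard error for each tested member of the 13 lists with at least 3 tested members, with each list's median and the median of all 104 tested miRNAs (-0.20). Of the fibroblast list 6 of 7 members lie above 0, and the muscle list has 2 members far below the others, miR-378a-3p and miR-133a-3p.

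miRNAs with GC-rich precursors were grouped after the data were seen, and no list test was run on them. In edgeR's quasi-likelihood test 0 of the 8 tested passed an adjusted p of 0.05, and DESeq2 called 6 of them. All 8 tested miRNAs with a precursor GC of at least 70% had negative log2 fold changes under each scaling, with a median of -3.42 under TMM and -2.19 under library totals, and 6 had an unadjusted p under 0.05. miR-4516, from a precursor opposite an intron of PKD1 at chromosome 16, 2133119 to 2133204, stood at 18433 ± 13590.0 CPM in failing and 137554 ± 222833 in non-failing libraries (log2 fold change -2.90, SE 1.09, adjusted p = 0.0949), and at -1.41 without non-failing library 2. The share of counts on all GC-rich precursors was 5.18% ± 3.44 in failing and 23.3% (3.73% to 63.1%) in non-failing libraries, a difference within the spread between libraries (exact permutation p = 0.123). Without non-failing libraries 2 and 6 the median of the 8 was -1.39.

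In the authors' deposited table, 36 of 439 miRNAs with an FDR were below 0.05, 4 higher and 32 lower in failing. The 4 higher were miR-100-5p, miR-335-5p, miR-654-3p and miR-342-3p, with log2 fold changes of 1.85, 2.34, 2.27 and 1.49 in the authors' deposited table. Its lower set included miR-10400-5p, miR-4492, miR-3960, miR-4508, miR-4488, miR-223-3p, miR-486-5p and 5 miRNAs of the miR-378 group, whose sequences are nearly identical so that counts between them are uncertain. Of the 36 in the authors' deposited table, 12 had enough counts for the test used here and had the same direction in it, and 24 fell below its count filter. Of its 32 lower miRNAs, 15 had their highest CPM in non-failing library 2, 11 in library 5, 4 in library 6 and 2 in another library.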

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

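Single libraries lay far from the other 5 of their group for 18 sets of 6 values. For normal values and independent sets, chance gives about 1 in 20 of the sets examined, or 6.6. CPM values can be skewed and the sets share the same libraries, so 6.6 is a rough guide only. Of the tests on the patterns below, only that of a GC trend was chosen before its result was seen. Non-failing library 5 accounted for 10 of the 18 values. It had 544286 CPM of miR-378a-3p (next highest 68806), 157989 of miR-133a-3p, 440227 of let-7b-5p, 101500 of let-7i-5p, 38927 of miR-423-5p, 23232 of miR-126-5p, 16525 of miR-671-5p and 9679.9 of miR-221-3p, all above the other non-failing libraries. Its miR-199a-3p was the lowest at 10648 CPM, and 6.46% of its counts fell on miRNAs below the count filter. Non-failing library 2 was the highest for miR-4516 (574626 CPM), miR-4508 (68947), miR-16-5p (76526) and miR-92a-3p (13789). Non-failing library 6 was the highest for let-7a-5p (114008 CPM), and non-failing library 3 for miR-99a-5p (3445 CPM). Non-failing library 4 had the highest share of leukocyte and platelet miRNAs, 3.18%. Among failing libraries, library 6 was the highest for miR-671-5p (1247 CPM).

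The 8 tested miRNAs with GC-rich precursors, of which edgeR's quasi-likelihood test called 0 (6 at an unadjusted p under 0.05) and DESeq2 6, had a median log2 fold change of -3.42 under TMM and -2.19 under library totals. Leaving out non-failing libraries 2 and 6 moved the median to -1.39, so these libraries may carry part of it, and non-failing library 3, with a GC-rich share of 29.3%, remained in that fit. A GC trend over all miRNAs was not settled either: Spearman's rho of the log2 fold change with precursor GC was -0.19 across tested miRNAs under 70% GC (bootstrap interval -0.37 to 0.000328), across miRNAs that are not independent replicates. Depth could not be told apart with 6 libraries, where the GC-rich share had a Spearman's rho of -0.14 with the total count (exact permutation p = 0.803, Pearson's r = -0.13, p = 0.760, and r = -0.82 without the 2 libraries farthest in depth), 1 relation being computed. Heart failure itself stays among the open explanations, as does a match of these sequences to ribosomal RNA, which was not analysed here.

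miR-378a-3p and miR-133a-3p, neither past an adjusted p of 0.05 in edgeR's quasi-likelihood test, had log2 fold changes of -4.67 and -3.01 and were highest in non-failing library 5, and DESeq2 called miR-378a-3p (adjusted p = 0.00153) while edgeR with no count filter called both. In that library miR-378a-3p took 22.5% of counts against a median of 0.346% in the other 5, and miR-133a-3p 6.53% against 0.650%. RNA of muscle cells as a candidate source stays open: miR-1-3p took 0.777% against a median of 4.68%, a ratio of 0.166, but within the range of the other 5 (0.666% to 6.64%). Without library 5 the mean log2 fold change of both was -1.28 (-1.89 and -0.68). Of the remaining non-failing libraries, library 3 had 68806 CPM of miR-378a-3p. Libraries 1, 2, 4 and 6 had 452 to 3935 CPM, below the failing mean of 4063. With all libraries, 3 of 6 failing libraries lay above the non-failing median for miR-378a-3p and 1 of 6 for miR-133a-3p. A smaller difference could not be separated from the effect of single libraries. Without library 5, edgeR's quasi-likelihood test called 10 miRNAs at an adjusted p of 0.05, and neither miR-378a-3p nor miR-133a-3p was among them. A difference with heart failure apart from library 5 thus stays open.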

How the results depend on the processing

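Fits without non-failing libraries 2 and 6 or 2, 5 and 6, those and shares without GC-rich rows, and thinned fits were chosen after seeing the data, and the other alternatives, single libraries left out included, beforehand. A 2-fold minimum can only remove calls of the main fit, so its count of 0 was fixed in advance. The count of 0 miRNAs past an adjusted p of 0.05 held under RLE, upper-quartile and library-total scaling, and under robust estimation. It also held with the GC-rich rows left out, under thinning, and without non-failing libraries 2, 5 and 6. It was 44 with no count filter (2 higher, 42 lower, of 687 tested), 23 with DESeq2 (6 higher, 17 lower), 23 at an adjusted p of 0.10 (5 higher, 18 lower), 2 without non-failing libraries 2 and 6 (2 higher), and 1 (1 higher, miR-23a-3p) each with a mean CPM of at least 10, limma-voom and quality weights. DESeq2 and no filter shared 10 calls. Leaving out single libraries gave 0 to 10 calls, 0 to 3 higher and 0 to 8 lower: 9 without non-failing library 1, 10 without non-failing library 5 and 0 without any other. The cause was not tested. Lists passing camera numbered 1 with all libraries, 0 with an estimated correlation, library totals or thinning, and 2 without non-failing libraries 2, 5 and 6 (miR-23/24/27 and 14q32, with the fibroblast list at an adjusted p of 0.0900). Without non-failing library 5 the single list passing was miR-23/24/27 (adjusted p = 0.0206) in place of the fibroblast list (0.111). Shares passing numbered 3 with let-7b-5p left out, adding smooth muscle and 14q32, and 1 outside GC-rich rows. Against TMM, the median log2 fold change moved by 0.59 with library totals and 0.25 with upper-quartile scaling. Of the refits of named miRNAs, 892 kept direction and side of the threshold, 50 passed it and 26 changed direction. With library totals, log2 fold changes were 0.14 for miR-29b-3p, 0.14 for let-7i-5p, 0.36 for let-7b-5p and 0.10 for miR-16-5p. With no filter they were 0.17, 0.0016 and 0.14 for miR-29b-3p, let-7i-5p and let-7b-5p. With a mean CPM of at least 10 they were 0.58 for miR-29b-3p, 0.38 for let-7i-5p, 0.45 for let-7b-5p, 0.26 for miR-30e-5p, 0.14 for miR-30c-5p, 0.18 for miR-92a-3p and 0.33 for miR-16-5p. With quality weights they were 0.31 for let-7b-5p and -0.0203 for let-7f-5p. Without non-failing libraries 2 and 6, miR-92a-3p and miR-16-5p stood at 0.24 and 0.24. Without libraries 2, 5 and 6, miR-29a-3p and let-7b-5p stood at -0.0739 and 0.54. Leaving out single libraries gave -0.32 to 0.33 for miR-29b-3p, -1.21 to 0.0253 for miR-221-3p, -0.69 to 0.37 for let-7b-5p, -0.88 to 0.0384 for miR-92a-3p, -0.67 to 0.0316 for miR-16-5p and -0.0584 to 0.31 for let-7f-5p. The cause of these turns was not tested. With the replicate number as a replicate block, 0 miRNAs passed and 16 had an unadjusted p under 0.05 (smallest adjusted p = 0.310). Same-numbered libraries correlated at -0.29 to 0.37, 3 of 6 over 0.1, and 1 of 6 correlated best with its own number. These values gave no clear sign that the numbers pair the samples, but 6 values are too few to exclude it. The count filter limits the comparison to 104 of 687 miRNAs, where a mean CPM of at least 10 kept 410. Read counts, other small RNA classes and values other than counts were not run as alternatives, since UMI counts of miRNAs were used.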

Other observations

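The miRNAs of this paragraph were chosen after their values were seen. In DESeq2, miR-185-5p had a log2 fold change of -1.48 (adjusted p = 0.0234) and miR-4448 one of -2.51 (adjusted p = 0.00991), and neither passed in edgeR's quasi-likelihood test. miR-22-3p, a miRNA abundant in heart muscle, was at -2.27 in DESeq2 (adjusted p = 0.0406) and at -2.39 in edgeR (SE 0.99, adjusted p = 0.127). miR-619-5p, below the count filter with all libraries, was at -4.55 without non-failing library 1 and at -4.58 without non-failing library 5 (edgeR adjusted p = 0.0327 and 0.0273).

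The test of miR-23a-3p by thinning and the test without 3 libraries were written before their results were seen, and the depth regression and the scaling test after, the regression once the thinned value was known. miR-23a-3p had a log2 fold change of 0.99 and did not pass an adjusted p of 0.05 with all libraries in edgeR's quasi-likelihood test. The composition of non-failing libraries 2, 5 and 6 is argued against by a log2 fold change of 1.17 without them (95% interval 0.58 to 1.76). Depth is argued against by a slope of 0.0863 on the log2 total count with group in the model (SE 0.0979), where the group term was 0.87. The median of 1.01 over 20 thinned draws (0.65 to 1.16) says nothing on depth, since thinning leaves the expected shares in place, and the lowest value of 1.14 relative to the median of all tested miRNAs over 4 scalings (highest 1.24) says nothing on scaling, since that median takes up a shift between libraries. Scaling and heart failure both stay open, as does anything else that differed between the 2 groups of samples, which the design cannot tell apart from heart failure.

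Other splits of the 12 libraries into 6 and 6 were compared with the real one, 100 of the 462 possible, the real one included. The split count at an adjusted p was chosen after its result was seen. For miRNAs past an adjusted p of 0.05 the real count was 0, which all 100 splits reach by construction, so this count says nothing about chance (highest other 7). For an unadjusted p under 0.05, 2 of 100 splits, the real one included, were as high as the real count of 28, the highest other being 30. So high a count was rare among the splits, but chance was not excluded, since the split comparisons were not adjusted for their number. For lists passing camera chance could not be excluded either, with 50 of 100 splits at or above the real count of 1 and the highest other at 3. For the fibroblast list 6 of 100 splits gave a camera p as small as the real 0.000532, the smallest other being 5.56e-05, and chance could not be excluded.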
